A study of Mus musculus with 8 samples.

How the data were processed

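The series measured RNA in mouse E9.5 PGCs, iPGCs, PGCLCs and EGCs, with 2 libraries per group. Per the labels, total RNA was amplified with an Ovation kit, spike-in RNA was added, and 8 libraries were sequenced together as 50-base single-end reads in 2 lanes. The table deposited by the authors holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, with 1 column per library. Per the submitters' processing notes, TopHat2, Cufflinks and the GRCm38 (mm10) genome were named. Versions, annotation, filters and any use of strand are not given in the sources used here. Spike-in values were not analysed here.

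The table had 20171 entries for 20153 gene identifiers. For the 15 identifiers with more than 1 entry, 18 extra entries were dropped. Of the identifiers, 19769 were found in GENCODE M21 (GRCm38), which supplied symbols, lengths and coordinates, since 27 symbols had been turned into dates. No read counts were given, so no count test was used. Approximate depths were read from the smallest step between low FPKM values of single-transcript genes over 1 kb. FPKM of housekeeping genes with many pseudogenes and of loci shorter than a read fragment is uncertain, because Cufflinks divides shared reads and corrects for effective length. An exact 0 may be a failed estimate, so such genes are called listed at 0 and no fold is given against a group at 0. A gene's log2 difference is on the log2(FPKM + 1) scale and understates the change of low genes.

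The following choices were made before the data were examined. Genes at 1 FPKM or more in at least 2 libraries (11083) were tested on log2(FPKM + 1) with limma 3.58.1 (trend and robust variance) in R 4.3.3. All 8 libraries shared 1 estimate of the spread, with 4 residual degrees of freedom and a median prior of 4.53. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Gene lists, 28 in number, were fixed in advance, and those with at least 5 tested members were compared with all other genes by camera, with a preset correlation of 0.01 between genes and adjustment over lists. No list call held with an estimated correlation in any comparison. The self-contained test fry was run beside it and called 5, 7, 5 and 1 lists in the main comparisons of EGCs, iPGCs and PGCLCs with PGCs and of PGCLCs with iPGCs. In part these were other lists than those of camera. In EGCs fry left out mesoderm and Hox (fry adjusted p = 0.0523) and BMP, FGF and LIF genes (0.0919). In iPGCs it left out early PGC (0.446), Myc and growth (0.476) and sex-linked genes (0.0804). In PGCLCs it left out mesoderm and Hox (0.0867) and sex-linked genes (0.227). Later germ cell genes in iPGCs were called by fry (0.0331) but not by camera. Genes of a list without an entry, such as the embryonic globins, Cdt1 and Tubb3, were not analysed here.

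Genes named in the text follow a fixed rule, except for Aff2 and some microRNAs, which were chosen after their values were seen. For the 4 main comparisons they are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold. They had a mean of at least 10 FPKM in the higher group, and every library of 1 group lay above every library of the other. Predicted genes, ribosomal protein genes, microRNAs, small nucleolar RNAs and pseudogenes were skipped. For EGCs against iPGCs or PGCLCs the top 3 each way were taken, and members of the lists could be named with their values.

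Simulated data with 200 changed genes in each of 5 draws were used to test the limma step for each comparison over 11083 genes. For EGCs against PGCs, 1.2% of genes changed by a log2 of 1 were recovered, 6.8% at 2, 64% at 4 and 98% at 6, and 5.3% of calls were false. For iPGCs against PGCs recovery at 2 and 4 was 5.2% and 68.4%, with 3% of calls false. For PGCLCs against PGCs it was 9.6% and 63.2%, with 6.7% of calls false. Library medians of log2(FPKM + 1) ran from 2.35 in PGC library 1 to 3.02 in PGCLC library 1. Values on this scale cannot be negative, so a typical gene cannot fall by 4 or 6. Recovery at these sizes therefore does not apply to falls of such genes. The recovery and false-call rates hold only for data built like the simulated ones. For EGCs against PGCs, over 20 simulations, camera called 1 list without a change and the list raised by a log2 of 1 in all 20. Simulated genes were drawn independently of each other, so this does not show how often camera calls lists falsely where genes are correlated. With 2 libraries per group, only large differences could be called, and the smallest called log2 differences were 2.44, 2.52 and 2.45 in these 3 comparisons.

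Other settings were a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, quantile normalization or equal library medians, no variance trend, a minimum log2 difference of 1, only the groups compared, a replicate block, and each library left out in turn. Library weights, removal of small RNA genes and removal of each library's GC or transcript length trend were chosen after seeing the data. The labels call the libraries biological replicates without saying that they came from separate cultures or litters, so p-values measure only the spread between these samples, which may be technical. Strain, cell origin and passage are confounded with the group wherever cells derived from BVSC stem cells are compared with PGCs or EGCs. Passage also differed between EGCs (6) and PGCs (0). The number of cells per library is confounded with the group in every comparison with PGCs and between PGCLCs and iPGCs. Sex-linked transcripts also differed between groups, so sex may be confounded with the group as well. The iPGCs and PGCLCs share strain and passage. Calculations outside R used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.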

Results

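RNA was sequenced from 8 mouse libraries in 4 groups of 2. Primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, came from embryos at E9.5. Embryonic germ cell (EGC) lines 4 and 7 had been derived from such PGCs, shared their Oct4-GFP by CD1 strain and were at passage 6. The other groups came from BVSC embryonic stem cells at passage 21. The iPGCs were made by a hanging drop method, and the PGC-like cells (PGCLCs) in aggregates by way of epiblast-like cells. About 250 PGCs, 1500 iPGCs, 300 to 500 PGCLCs and 500 EGCs went into each library. Values are FPKM, so read totals are not stated. The smallest steps between low values gave approximate depths of 16.5 and 14.0 M reads for PGC libraries 1 and 2, and 2.59 and 14.6 M reads for the iPGC libraries. They gave 7.37 and 15.0 M reads for the PGCLC libraries and 12.9 and 15.6 M reads for EGC lines 4 and 7. Genes at 1 FPKM or more numbered 8259 and 7991 in the PGC libraries, 9836 and 10039 in iPGCs, 9157 and 9722 in PGCLCs, and 8677 and 9280 in EGCs.

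Across genes, log2(FPKM + 1) of libraries of the same group correlated with a mean Pearson r of 0.793 ± 0.070 (SD, 4 pairs), against a mean of 0.723 between groups. Genes are not independent replicates, so no test was made. The mean r was 0.819 between iPGC and PGCLC libraries, 0.692 between PGC and iPGC, 0.674 between PGC and PGCLC, and 0.656 between PGC and EGC libraries. It was 0.769 between iPGC and EGC and 0.727 between PGCLC and EGC libraries. The 2 PGC libraries were the least alike pair within a group, at 0.710, and PGC library 2 was closer to iPGC library 1 (0.715), iPGC library 2 (0.718) and PGCLC library 2 (0.720) than to PGC library 1. EGC line 7 was likewise closer to iPGC library 2 (0.811) and iPGC library 1 (0.793) than to EGC line 4 (0.784). Both iPGC libraries correlated at 0.796 or more with both PGCLC libraries, whose own r was 0.794. In genes at 10 FPKM or more the median absolute log2 difference between replicates was 0.75 in PGCs, 0.38 in iPGCs, 0.62 in PGCLCs and 0.52 in EGCs. PGC library 1 also held transcripts typical of other embryonic cells that PGC library 2 lacked. Afp, a yolk sac and liver protein, was at 82.6 against 0 FPKM, and Lyz2, a macrophage enzyme, at 62.1 against 0.713. The platelet chemokine Pf4 was at 27.2 against 0, and the mesoderm factor T at 37.9 against 0.

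**Figure D1:**
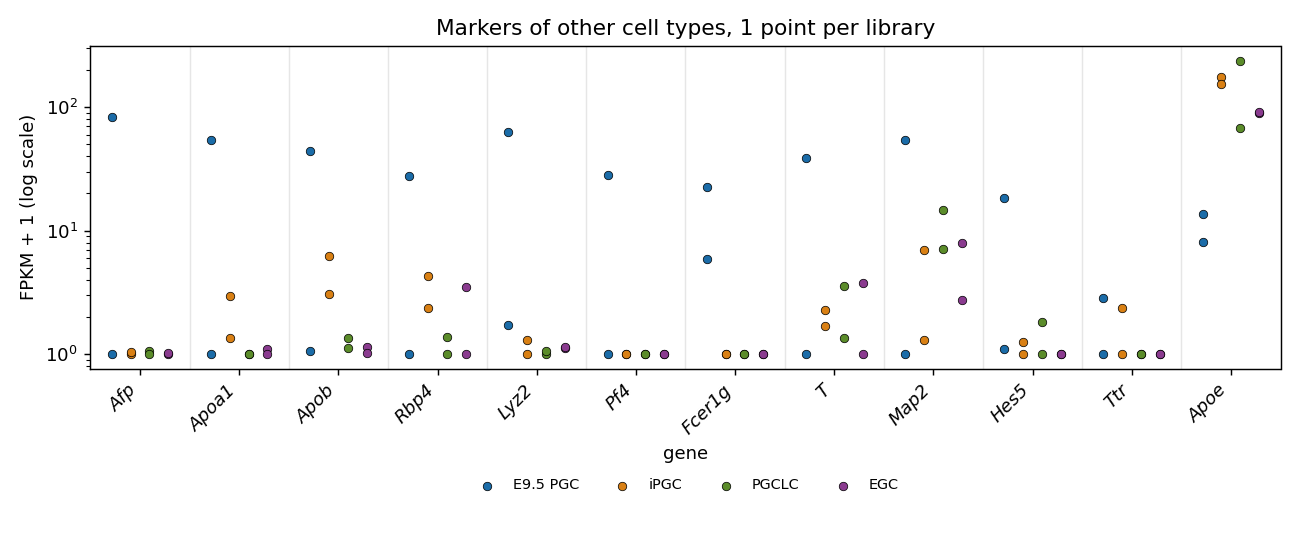
Transcripts typical of other embryonic cells in the 8 libraries, as FPKM + 1 on a log axis with 1 point per library. Afp, Apoa1 and Pf4 reached 82.6, 53.0 and 27.2 FPKM in PGC library 1 and were listed at 0 in PGC library 2.

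EGCs were compared with E9.5 PGCs to ask what differs once germ cells have reverted to a pluripotent line. As lists, early PGC genes were lower in EGCs, and glycolysis, naive pluripotency and primed epiblast genes higher, in camera with a preset correlation but in none with an estimated one (adjusted p = 0.284 for each with an estimated correlation). Over all genes 2 of 15, 1 of 20, 0 of 18 and 2 of 13 members passed in limma. Dppa3, a germ cell protein that protects methylation in the zygote, fell by 2.91 ± 0.51 (log2 difference ± SE, n = 2 against 2), from 409 and 574 to 40.3 and 101 FPKM. Tdgf1, the Nodal co-receptor Cripto, rose by 5.80 ± 0.69, from 0.534 and 4.78 to 189 and 145 FPKM. In limma, 82 of 11083 tested genes changed at a Benjamini-Hochberg adjusted p below 0.05, 58 higher and 24 lower in EGCs. The median log2 difference of all tested genes was 0.07.

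Among the genes with the largest rise in EGCs, Upp1, which encodes uridine phosphorylase, rose by 6.29 ± 0.63 (adjusted p = 0.00714). The metallothionein gene Mt2 rose by 5.77 ± 0.53 (adjusted p = 0.00501), and the secreted phospholipase gene Pla2g1b by 6.13 ± 0.87 (adjusted p = 0.0301). Sgk1, a serum-induced kinase, went from 7.01 and 0.260 to 101 and 143 FPKM, and Uap1l1 from 0 and 0.952 to 90.2 and 31.7 FPKM. Fam25c was listed at 0 in both PGC libraries and at 18.8 and 84.5 FPKM in EGCs. Mylpf, a fast muscle myosin light chain (chromosome 7, 127208890 to 127214298, GRCm38), rose by 6.61 ± 0.98. It ends beside Sept1, which begins at 127214447, and the sources do not say whether reads were assigned by strand. PRINS was listed at 0 in both PGC libraries and at 258 and 288 FPKM in EGCs (adjusted p = 0.00128). Scarna8 was at 0 in PGCs and at 154 and 58.6 FPKM in EGCs. These are annotated as 89 and 131 bases long, and FPKM at such short loci is uncertain. Rgma, a BMP co-receptor, fell by 5.48 ± 0.96 (adjusted p = 0.0488), and the retinoic acid binding protein gene Crabp1 by 4.52 ± 0.75. Atp8a1, a phospholipid flippase, fell by 4.34 ± 0.64, and Hmgn5, a nucleosome binding protein, by 3.96 ± 0.49, from 117 and 127 to 5.00 and 9.46 FPKM. The kinase gene Lrrk2 fell by 3.77 ± 0.59, Nrk by 3.77 ± 0.57, AU015836 by 4.27 ± 0.67 and the GTPase gene Hras by 3.70 ± 0.56. Tnnt3, a muscle troponin, was at 40.1 and 10.9 FPKM in PGCs and listed at 0 in both EGC libraries.

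Of 15 tested early PGC genes, Dppa3 and the integrin gene Itgb3 fell and 13 did not pass over all genes. Adjusted over the list alone, 9 fell. Prdm1, the repressor Blimp1 that specifies PGCs, fell by 3.01 ± 0.57 within the list, Tfap2c by 1.99 ± 0.45 and the receptor gene Kit by 2.38 ± 0.57. The list was lower than other genes in camera (median -1.99, adjusted p = 4.28e-07; adjusted p = 0.284 with an estimated correlation). Of 20 glycolysis genes, 1 rose over all genes (Eno2, listed at 0 in PGCs and at 13.3 and 8.90 FPKM in EGCs), and 10 rose adjusted over the list alone. They included the glucose transporter gene Slc2a1 (1.90 ± 0.39) and Eno1 (1.68 ± 0.37). The glycolysis list was higher (median 1.20, adjusted p = 3.13e-06; adjusted p = 0.284 with an estimated correlation). Of 13 primed epiblast genes, 2 rose over all genes and 8 adjusted over the list alone. The de novo DNA methyltransferase gene Dnmt3b rose by 4.36 ± 0.76, and the Nodal antagonist Lefty1 was listed at 0 in PGCs and at 32.6 and 31.8 FPKM in EGCs. Of the 13, 10 had positive and 3 negative differences, and Fgf5, another member, lay at 0.02 ± 0.53 relative to all genes. That list had a median of 2.47 (adjusted p = 0.000485; adjusted p = 0.284 with an estimated correlation). Of 18 naive pluripotency genes, 0 passed over all genes and 5 rose adjusted over the list alone, among them Dppa5a (3.13 ± 0.60), Fgf4 (2.71 ± 0.60) and Zfp42 (2.00 ± 0.59). The naive list had a median of 1.505 (adjusted p = 0.00178; adjusted p = 0.284 with an estimated correlation).

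Lists of BMP, FGF and LIF target genes and of mesoderm and Hox genes were lower in EGCs. The first list also holds receptor genes (Fgfr1, Fgfr2, Lifr and Il6st) and the ligand gene Bmp4, so it does not measure target genes alone. No member of either passed over all genes in limma, and 3 of 19 and 3 of 11 fell adjusted over the list alone. Fgfr2 fell by 3.35 ± 0.69 and Etv5 by 2.23 ± 0.51 within the first list, and Msx2 by 2.95 ± 0.64 and Tbx4 by 3.42 ± 0.67 within the other. The BMP, FGF and LIF list had an adjusted p of 0.00951 (adjusted p = 0.33 with an estimated correlation), and the mesoderm list 0.0125 (adjusted p = 0.284 with an estimated correlation). The mesoderm call was lost without PGC library 1 (adjusted p = 0.0967), in which T was at 37.9 FPKM, without EGC line 7 (0.0545) and with a pseudocount of 0.1 (0.0532). The BMP, FGF and LIF call was lost without PGC library 2 (0.0977) and without EGC line 4 (0.0846).

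Imprinted genes moved both ways. Among 14 maternally expressed imprinted genes, Mirg rose by 5.26 ± 0.56 (adjusted p = 0.00861), from 0.534 and 0.587 to 66.8 and 51.4 FPKM. H19, a growth-restraining noncoding RNA, fell by 4.17 ± 0.86 and Grb10 fell by 3.66 ± 0.69 adjusted over the list alone, where 2 genes rose and 3 fell (camera adjusted p = 0.239). Among 20 paternally expressed imprinted genes, Peg3 fell by 2.83 ± 0.47 (adjusted p = 0.0454), and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.872). Igf2 was at 81.0 and 9.13 FPKM in PGCs and at 0.0907 and 0.396 FPKM in EGCs, which did not pass (adjusted p = 0.14). Of 28 genes of DNA methylation and demethylation, Dnmt3b and its cofactor Dnmt3l rose and Dppa3 fell, and 3 rose and 3 fell adjusted over the list alone. Dnmt3l was listed at 0 in both PGC libraries and at 14.1 and 42.5 FPKM in EGCs. That list did not stand apart (adjusted p = 0.695), and its median (-0.31) and mean (0.12) differed in sign.

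Of 15 core pluripotency genes, Tdgf1 rose over all genes, and Nanog rose by 2.04 ± 0.48 while Sall4 fell by 1.71 ± 0.36 adjusted over the list alone (camera adjusted p = 0.507). Pou5f1 was at 24.7 and 72.1 FPKM in PGCs and at 83.5 and 65.8 FPKM in EGCs (adjusted p = 0.672). In 7 further lists no member passed over all genes in limma, nor adjusted over the list alone. Their camera adjusted p was 0.695 for 20 later germ cell genes, 0.802 for 26 genes of histone methylation and Polycomb, 0.695 for 25 cell cycle genes, and 0.977 for 10 cell cycle inhibitors. It was 0.872 for 23 oxidative phosphorylation genes, 0.872 for 15 immediate early and stress genes, and 0.381 for 16 apoptosis regulators. The median and mean of 4 of these lists differed in sign, at -0.29 and 0.11 for histone methylation, -0.34 and 0.03 for the cell cycle, -0.19 and 0.15 for its inhibitors, and -0.14 and 0.08 for stress genes. Oxidative phosphorylation genes had a median of 0.11 and a mean of 0.03, while camera placed them lower. The 18 Myc and growth genes had an adjusted p of 0.0698, and 13 genes of germ cell adhesion and migration, with Itgb3 lower, 0.0908. The former were called lower with no filter (0.0355), equal medians (0.0484), only the 2 groups compared (0.0499) and without PGC library 1 (0.0416), and the latter with no filter (0.0311). None of 15 genes typical of 2-cell-like cells passed the expression filter.

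Markers of other cell types were also compared. Trh, counted among gut endoderm markers, rose by 4.67 ± 0.76 and the neuronal gene Stmn2 by 4.99 ± 0.69 in EGCs. The camera adjusted p was 0.637 for gut endoderm, 0.163 for neural, 0.0908 for extraembryonic endoderm, 0.761 for endothelial, 0.872 for trophoblast and 0.375 for fibroblast or mesenchyme markers. Median and mean differed in sign for gut endoderm (-0.17 and 0.83), endothelial (-0.41 and 0.07) and trophoblast markers (-0.12 and 0.07). The EGCs were grown on feeder fibroblasts, per the labels, and Col1a1, an abundant fibroblast collagen, was at 0.0142 and 0 FPKM in them. Only 2 blood genes were tested, too few for camera, and Fcer1g was at 21.4 and 4.85 FPKM in PGCs and listed at 0 in the 6 other libraries. The 6 sex-linked markers had an adjusted p of 0.0908, and 0.00803 without EGC line 7. Extraembryonic endoderm markers were called lower without PGC library 2 (0.00329), when only library 1 with its Afp stood for PGCs, and with no filter (0.0355), as were fibroblast (0.0134) and blood markers (0.00884).

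The 82 calls rested on all of the libraries in the fit, with 66 without PGC library 1 and 107 without PGC library 2. The count was 7 without EGC line 4, 11 without EGC line 7, 15 without iPGC library 1, 15 without iPGC library 2, 21 without PGCLC library 1 and 20 without PGCLC library 2. A pseudocount of 5 left 31 calls, no expression filter 14, library weights 23 and a fit of the 4 libraries alone 0 in limma (1906 genes had an unadjusted p below 0.05 in the fit of all libraries), and quantile normalization gave 57 higher and 37 lower.

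**Figure D2:**
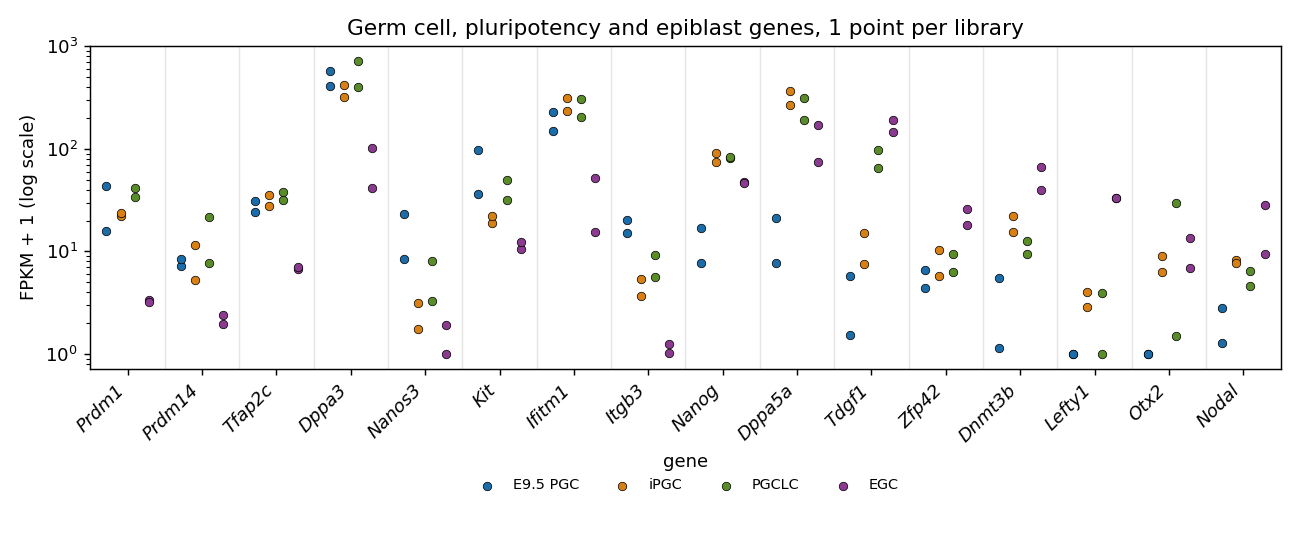
Germ cell and pluripotency genes in the 8 libraries, as FPKM + 1 on a log axis with 1 point per library. Prdm1 lay at 2.34 and 2.20 FPKM in EGCs and between 14.9 and 42.5 FPKM in the other libraries, and Nanog at 6.69 and 16.1 FPKM in PGCs and between 45.3 and 90.9 FPKM in the others.

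The iPGCs were compared with E9.5 PGCs to ask how closely cells made in hanging drops match endogenous germ cells. Mt2 rose from 9.45 and 3.01 FPKM in PGCs to 614 and 973 FPKM in iPGCs, and the pluripotency factor gene Nanog from 6.69 and 16.1 to 73.2 and 90.9 FPKM. Lats2, a kinase of the Hippo pathway, fell from 29.2 and 20.8 to 1.39 and 0.637 FPKM. In limma 88 of 11083 genes changed, 83 higher and 5 lower in iPGCs. The median of all tested genes was itself 0.47 higher in iPGCs on the log2 scale, so log2 differences in this comparison are given relative to that shift. The limma p-values and calls, over all genes or a list alone, test the differences before the shift is subtracted. Relative differences of single genes were not tested. Strain, origin and passage differed together with the group. Sex may differ too. The PGC libraries held both Xist and the Y-linked Eif2s3y, and the iPGCs held Eif2s3y (9.97 and 7.27 FPKM) with Xist at 0.244 FPKM or less.

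Relative to all genes, Mt2 rose by 6.43 ± 0.53 (n = 2 against 2, limma adjusted p = 0.00236) and Uap1l1 by 6.40 ± 0.68 (adjusted p = 0.00868). Fabp3, a fatty acid binding protein gene, rose by 5.97 ± 0.65, from 0.198 and 0.107 to 88.3 and 111 FPKM. The tight junction genes Cldn4 and Cldn6 rose by 5.27 ± 0.51 and 5.40 ± 1.01. Ccng1, which encodes cyclin G1 and is a target of p53, rose by 4.55 ± 0.53. The neighbours Mylpf and Sept1 rose by 7.21 ± 0.98 and 5.00 ± 0.73. Dnmt3l was listed at 0 in both PGC libraries and at 51.8 and 53.4 FPKM in iPGCs, and Wfdc2 at 0 in PGCs and at 60.4 and 33.0 FPKM in iPGCs. The mitotic kinase gene Cdk1 rose by 2.77 ± 0.57 (adjusted p = 0.0482) and the apolipoprotein gene Apoe by 3.50 ± 0.60 (adjusted p = 0.0331). Xist, the RNA that silences an X chromosome, fell from 21.4 and 13.5 to 0.228 and 0.244 FPKM (adjusted p = 0.0465), a relative difference of -4.33 ± 0.67. S100a9, a calcium binding protein of myeloid cells, was at 15.6 and 8.77 FPKM in PGCs and listed at 0 in iPGCs. In PGC library 1 the myeloid transcript Lyz2 was at 62.1 FPKM.

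The 8 tested gut endoderm markers were higher in iPGCs, with Cldn6 and Spink3 past the test over all genes and 3 adjusted over the list alone. Spink3, a secreted protease inhibitor gene, went from 1.146 and 0 to 60.3 and 32.8 FPKM, and the list median was 1.07 relative to all genes (adjusted p = 0.00623; adjusted p = 0.344 with an estimated correlation). Naive pluripotency genes were higher, with a relative median of 1.03 (adjusted p = 0.017; adjusted p = 0.344 with an estimated correlation). Of these 18, Dppa5a rose over all genes, by 4.15 ± 0.60, and 3 rose adjusted over the list alone, Fgf4 among them (2.52 ± 0.60). Glycolysis genes were higher (relative median 0.40, adjusted p = 0.0356; adjusted p = 0.473 with an estimated correlation), with 0 of 20 past the test over all genes in limma and 6 adjusted over the list alone, such as Slc2a1 (1.14 ± 0.39) and Eno1 (1.00 ± 0.37).

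Early PGC genes were lower relative to all genes (relative median -0.66, adjusted p = 0.0159; adjusted p = 0.473 with an estimated correlation), although 0 of 15 passed in limma, over all genes or adjusted over the list alone. Dppa3 was at 423 and 317 FPKM in iPGCs against 409 and 574 FPKM in PGCs, and Prdm1 at 21.2 and 22.8 against 14.9 and 42.5 FPKM. Myc and growth genes were also lower (relative median -0.67, adjusted p = 0.0233; adjusted p = 0.473 with an estimated correlation), with 0 of 18 past the test either way. The 6 sex-linked markers were lower (relative median -1.73, adjusted p = 0.00623; adjusted p = 0.344 with an estimated correlation), with Xist lower over all genes, and Xist and Kdm5d adjusted over the list alone. Later germ cell genes did not pass as a list (adjusted p = 0.0817), and 6 of 20, among them Dazl and Smc1b, were higher adjusted over the list alone. The list was called higher with a pseudocount of 0.1 (0.0249), no filter (0.0173), equal medians (0.0438), only the 2 groups compared (0.0477) and GC trends removed (0.0199). Mesoderm and Hox genes did not pass either (adjusted p = 0.0883), and were called lower with no filter (0.0164), with GC (0.034) or length (0.0232) trends removed and without iPGC library 1 (0.00693). Of 13 extraembryonic endoderm markers Apoe alone rose (camera adjusted p = 0.57), while Afp was at 82.6 FPKM in PGC library 1 and at 0.0284 FPKM or less in both iPGC libraries. Fibroblast markers did not pass (adjusted p = 0.168), and with no filter they (0.00142) and blood markers (0.00507) were called lower.

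Without PGC library 2 the 6 list calls were all lost, with adjusted p of 0.44 for early PGC genes, 0.0766 for naive pluripotency and for gut endoderm, 0.217 for Myc and growth, 0.119 for glycolysis and 0.059 for sex-linked markers. Early PGC genes and Myc and growth genes were also lost with quantile normalization (both 0.0545), and Myc and growth without iPGC library 2 (0.152). The glycolysis call was lost with equal medians (0.0712), with a replicate block (0.0574), without PGC library 1 (0.065), without iPGC library 1 (0.067), without PGCLC library 1 (0.0529) and without PGCLC library 2 (0.0521). It was also lost with a pseudocount of 5 (0.0508), without variance trend (0.0564), with only the 2 groups compared (0.0535) and with GC (0.0968) or length (0.0613) trends removed. The gut endoderm call was lost with no expression filter (0.131).

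The 88 gene calls were 62 without PGC library 1, 222 without PGC library 2, 5 without iPGC library 1, 6 without iPGC library 2, 22 without PGCLC library 1, 23 without PGCLC library 2, 31 without EGC line 4 and 32 without EGC line 7. With library medians set equal, 34 genes were higher and 12 lower, with quantile normalization 37 and 8, and a replicate block left 10 calls.

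The PGCLCs were compared with E9.5 PGCs for the same question about cells made in aggregates. The germ cell RNA-binding protein gene Dazl rose from 0 and 0.156 FPKM in PGCs to 11.9 and 9.65 FPKM in PGCLCs. Tdgf1 rose from 0.534 and 4.78 to 95.7 and 64.0 FPKM, and Nanog from 6.69 and 16.1 to 81.2 and 82.6 FPKM. Cd24a, a cell surface glycoprotein gene, fell from 163 and 169 to 1.97 and 13.0 FPKM. In limma 117 of 11083 genes changed, 104 higher and 13 lower in PGCLCs. The all-gene median was 0.44 higher in PGCLCs, and log2 differences here are relative to that shift. The limma p-values and calls again test the differences before it is subtracted.

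Acadvl, a mitochondrial enzyme of fatty acid oxidation, rose by 6.13 ± 0.63 (n = 2 against 2, limma adjusted p = 0.0165), to 107 and 85.9 FPKM. The DNA polymerase subunit gene Pold2 rose by 5.16 ± 0.64, from 1.48 and 0.160 to 134 and 48.6 FPKM. The autophagy receptor gene Calcoco2 rose by 4.98 ± 0.77, the RNase P subunit gene Rpp25 by 4.66 ± 0.83, Upp1 by 4.45 ± 0.63 and Uap1l1 by 5.44 ± 0.68. Apoc1 rose by 4.41 ± 0.80, to 171 and 129 FPKM, and Apoe by 3.16 ± 0.60. The neighbours Mylpf and Sept1 rose by 7.63 ± 0.98 and 4.90 ± 0.73. Scarna8, 131 bases long, was listed at 0 in PGCs and at 64.8 and 141 FPKM in PGCLCs, and Dnmt3l at 0 in PGCs and at 13.4 and 15.6 FPKM in PGCLCs. Clip3 fell by 5.71 ± 0.89 relative to all genes, Fndc3c1 by 5.46 ± 0.93, Cd24a by 5.13 ± 0.69 and the corepressor gene Runx1t1 by 4.46 ± 0.65. Lats2 fell by 4.34 ± 0.62, Tmem29 by 4.24 ± 0.55, Xist by 4.21 ± 0.67 and Prom1, a stem cell surface marker, by 4.02 ± 0.61. S100a9 and Gp49a were listed at 0 in both PGCLC libraries, and Gp49a was at 21.8 and 5.42 FPKM in PGCs. Lyz2, another myeloid transcript, was at 62.1 FPKM in PGC library 1 and at 0.0536 FPKM or less in PGCLCs.

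Later germ cell genes were higher in PGCLCs, with Dazl past the test over all genes and 4 of 20 adjusted over the list alone. The others were Asz1 (2.48 ± 0.58), Rpl10l (2.08 ± 0.66) and the meiotic cohesin gene Smc1b (2.59 ± 0.57). The list had a relative median of 0.93 (adjusted p = 0.00877; adjusted p = 0.498 with an estimated correlation). Naive pluripotency genes were higher, with Fgf4 (2.90 ± 0.60) and Dppa5a (3.83 ± 0.60) past the test over all genes and 3 of 18 adjusted over the list alone. Their relative median was 0.94 (adjusted p = 0.00893; adjusted p = 0.498 with an estimated correlation). Glycolysis genes were higher too (relative median 0.67, adjusted p = 0.00877; adjusted p = 0.498 with an estimated correlation), with 0 of 20 over all genes in limma and 6 adjusted over the list alone. Mesoderm and Hox genes were lower (relative median -1.26, adjusted p = 0.014; adjusted p = 0.498 with an estimated correlation), with 0 of 11 over all genes and Msx2, Snai2 and Tbx4 adjusted over the list alone, while T was at 37.9 FPKM in PGC library 1 and 0 in library 2. Sex-linked markers were lower (relative median -0.66, adjusted p = 0.0212; adjusted p = 0.498 with an estimated correlation), with Xist over all genes and 2 of 6 adjusted over the list alone. The Y-linked Eif2s3y was at 21.3 and 30.5 FPKM in PGCLCs, and sex may differ with the group. Among other cell types, extraembryonic endoderm markers did not pass (adjusted p = 0.0662) and were called lower without PGC library 2 (0.00338) and with no filter (0.0135). With no filter fibroblast (0.000801) and blood markers (0.00269) were also called lower. Myc and growth genes did not pass (adjusted p = 0.0662) and were called lower with equal medians (0.041), without PGC library 1 (0.0482) and without PGCLC library 1 (0.0185). Of 15 core pluripotency genes, Nanog (2.42 ± 0.48), Dppa2 (3.13 ± 0.60) and Tdgf1 (4.30 ± 0.69) rose, and the list did not pass (adjusted p = 0.757). Early PGC genes did not pass (adjusted p = 0.0662), with 0 of 15 called either way in limma and a relative median of -0.28. They were called lower with equal medians (0.041), with length trends removed (0.0216), without PGC library 1 (0.00725) and without PGCLC library 1 (0.0277), so no contrast with iPGCs was shown. Prdm1 was at 40.6 and 33.0 FPKM in PGCLCs against 14.9 and 42.5 FPKM in PGCs.

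Without PGCLC library 2 the 5 list calls were lost, with adjusted p of 0.21 for glycolysis and 0.0608 for each of the others. Without PGC library 1 the later germ cell list had an adjusted p of 0.2, and mesoderm and sex-linked genes each 0.0806, and without PGC library 2 sex-linked genes had 0.0616. With a pseudocount of 0.1 the mesoderm (0.0556) and sex-linked (0.0516) calls were lost, and with a filter at 5 FPKM the later germ cell call (0.0578), and with GC trends removed the sex-linked call (0.0522). At the filter of 5 FPKM the mesoderm and sex-linked lists kept too few members to be tested in any comparison.

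The 117 gene calls were 59 without PGC library 1, 289 without PGC library 2, 5 without iPGC library 1, 5 without iPGC library 2, 0 without PGCLC library 1, 0 without PGCLC library 2, 34 without EGC line 4 and 38 without EGC line 7 (2156 genes had an unadjusted p below 0.05 in the limma fit of all libraries). With library medians set equal, 36 were higher and 18 lower, with quantile normalization 29 and 7, and a replicate block left 2.

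**Figure D3:**
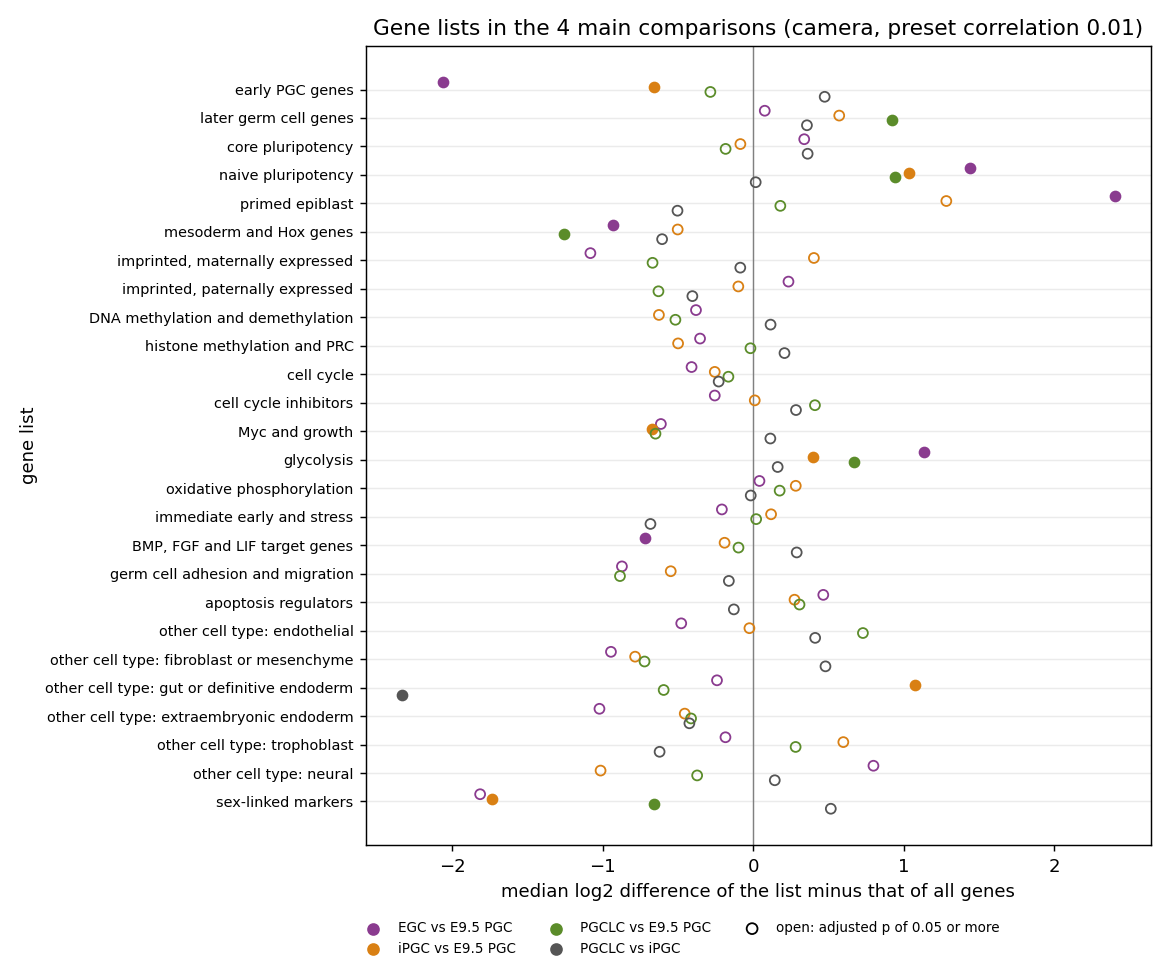
Median log2 difference of each gene list minus the median of all tested genes, in the 4 main comparisons. Open points have a camera adjusted p of at least 0.05 with a preset correlation of 0.01, and the early PGC list lay at -2.06 in EGCs against PGCs.

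The same genes often changed in iPGCs and PGCLCs against PGCs. Of the genes called in each, 53 were higher and 5 lower in both, and 0 moved in opposite directions. The shared higher genes included Mt2, Dnmt3l and Nanog. The shared lower genes were Aff2, Lats2, S100a9, Xist and Mir5110, of which Aff2 and Mir5110 fall outside the rule for named genes and were chosen after their values were seen. Both comparisons used the same PGC libraries. Independent lists of these sizes would share 0.785, a value that leaves the shared libraries out of account. The covariance of the log2 differences was 1.14, against 0.576 ± 0.011 (SD) in 100 simulations of unchanged groups with shared PGC libraries, a difference of 0.567, and their correlation was 0.771 against 0.675. With only 2 PGC libraries the controls were not split between the comparisons, and part of the excess over chance may come from these shared controls. Of the shared genes, 20 higher and 4 lower ones were also called in EGCs against PGCs. The 58 shared calls were 167 without PGC library 2, 2 without iPGC library 1, 2 without iPGC library 2, 0 without PGCLC library 1, 0 without PGCLC library 2, 22 without EGC line 4 and 24 without EGC line 7. They were 32 with equal medians and 27 with quantile normalization.

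The PGCLCs and iPGCs, made by different methods from stem cells of the same strain and passage, differed in few single genes. The gut endoderm markers were lower in PGCLCs. Spink3 was at 60.3 and 32.8 FPKM in iPGCs and listed at 0 in both PGCLC libraries (adjusted p = 0.0635 over all genes). Adjusted over the list alone, 4 of 8 fell, including the epithelial keratin genes Krt19, which fell by 2.73 ± 0.63, Krt18, by 3.26 ± 0.94, and Krt8, by 2.10 ± 0.54 (n = 2 against 2). The list had a median of -2.34 (adjusted p = 1.76e-07; adjusted p = 0.101 with an estimated correlation). Krt18 was also at 12.6 and 0.889 FPKM in the PGC libraries. In limma 2 of 11083 genes changed, and 519 had an unadjusted p below 0.05. Scarna8 was listed at 0 in iPGCs and at 64.8 and 141 FPKM in PGCLCs, and Mir3091, named although the rule for named genes leaves microRNAs out and chosen after its values were seen, was at 1016 and 315 FPKM in iPGCs and at 0 in the other libraries. FPKM at such short loci is uncertain. The list call held without any single library, whereas the count of genes was 0 without PGCLC library 1, 0 without PGCLC library 2, 4 without EGC line 4, 5 without EGC line 7 and 0 with no expression filter or with a replicate block.

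Adjusted over their lists alone, Tdgf1 rose by 2.89 ± 0.69 in PGCLCs against iPGCs, and the endothelial receptor gene Tek by 2.77 ± 0.74. The extraembryonic endoderm gene Dab2 fell by 3.01 ± 0.69 and Cubn by 1.97 ± 0.55. These lists did not pass in camera, with adjusted p of 0.227 for core pluripotency, 0.166 for endothelial markers and 0.157 for extraembryonic endoderm. The last was called lower with a pseudocount of 0.1 (0.0399), with only the 2 groups compared (0.0372), without PGC library 1 (0.016) and without PGC library 2 (0.0246), and glycolysis genes were called higher without PGCLC library 1 (0.0295). Early PGC genes had an adjusted p of 0.402 and later germ cell genes 0.274. Groups of 2 separated completely in 36.9% of genes, where chance gives 33.3%.

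EGCs differed from iPGCs in 13 genes (7 higher, 6 lower) and from PGCLCs in 11 (7 higher, 4 lower). Without small RNA genes these counts were 2 and 3, as they were with length trends removed. The all-gene median was lower in EGCs by -0.40 and -0.38, and the log2 differences here are relative to it. The limma calls test the differences before it is subtracted. Hspa8, a constitutive heat shock chaperone, was at 21.6 and 21.1 FPKM in EGCs against 345 and 271 FPKM in iPGCs and 387 and 237 FPKM in PGCLCs, relative differences of -3.37 ± 0.38 and -3.38 ± 0.38 (n = 2 against 2). Against iPGCs, Spink3 fell by 4.95 ± 0.64 and S100a6 by 4.54 ± 0.64. Against PGCLCs, the cell adhesion gene Adam23 rose by 5.13 ± 0.62, and the antiviral zinc finger gene Zc3hav1 fell by 3.64 ± 0.49. Tnnt3 was at 63.9 and 35.2 FPKM in PGCLCs and listed at 0 in EGCs. PRINS was at 258 and 288 FPKM in EGCs and listed at 0 in the other libraries. Primed epiblast genes were higher in EGCs against iPGCs (adjusted p = 9.57e-05; adjusted p = 0.325 with an estimated correlation) and against PGCLCs (adjusted p = 1.09e-07; adjusted p = 0.238 with an estimated correlation). Early PGC genes were lower against iPGCs (adjusted p = 0.000599; adjusted p = 0.452 with an estimated correlation) and against PGCLCs (adjusted p = 0.000454; adjusted p = 0.44 with an estimated correlation). Later germ cell genes were lower against PGCLCs (adjusted p = 0.00954, or 0.44 with an estimated correlation). So was the list of BMP, FGF and LIF target genes, which includes receptors (adjusted p = 0.0288, or 0.44 with an estimated correlation). The 6 neural markers, Stmn2 among them, were higher against iPGCs (adjusted p = 9.57e-05; adjusted p = 0.262 with an estimated correlation) and against PGCLCs (adjusted p = 0.0015; adjusted p = 0.238 with an estimated correlation). Against iPGCs, gut endoderm markers were lower (adjusted p = 0.0312; adjusted p = 0.405 with an estimated correlation) and glycolysis genes higher (adjusted p = 0.000599; adjusted p = 0.452 with an estimated correlation). The count against iPGCs was 5 without iPGC library 1, 6 without iPGC library 2 and 6 without EGC line 4. The count against PGCLCs was 39 without PGC library 1, 35 without PGC library 2, 0 without PGCLC library 1, 0 without PGCLC library 2 and 5 without EGC line 4. With library medians set equal, 9 genes were higher and 5 lower against iPGCs, and 7 higher and 1 lower against PGCLCs.

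**Figure D4:**
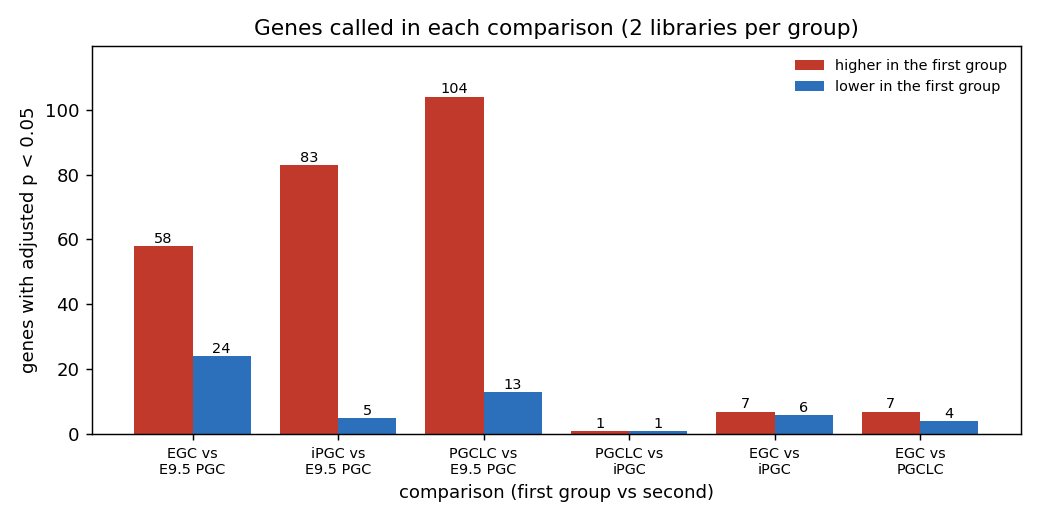
Number of genes called higher or lower in each of the 6 comparisons by limma at an adjusted p below 0.05. Higher calls outnumbered lower ones by 83 to 5 in iPGCs and by 104 to 13 in PGCLCs against PGCs, and 2 genes were called between PGCLCs and iPGCs.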

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

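The library weights, the removal of small RNA genes and the removal of GC and length trends were chosen after seeing the data. Of the 88 results for named genes none reversed in any setting, but 83 no longer passed with only the 2 groups compared, 71 with no filter, 75 without either iPGC library, 69 without either PGCLC library, 66 without EGC line 4 and 62 without EGC line 7. With 2 libraries per group most counts moved, and unless said otherwise the cause was not tested. Without the expression filter more genes enter the adjustment, and a fit of only the groups compared has fewer residual degrees of freedom. The removal of GC trends, a fit without trend and robust variance, and a minimum log2 difference of 1 moved no total of genes or lists called by over 1.5 times, although counts by direction could move more, as with the lower calls of EGC against PGC, 24 in the fit used and 13 without trend and robust variance. In the order EGC, iPGC and PGCLC against PGC, genes changed numbered 31, 34 and 32 with a pseudocount of 5, 14, 18 and 0 with no filter, and 0, 0 and 0 with only the 2 groups compared (1906, 2156 and 2156 unadjusted in the limma fit of all libraries). With a pseudocount of 0.1 iPGC and PGCLC gave 166 and 183, with quantile normalization 45 and 36, and with equal medians 46 and 54. Library weights gave 23 for EGC and 21 for PGCLC against PGC and 30 for EGC against iPGC, and removal of length trends 50 for iPGC against PGC. PGCLC against iPGC gave 1 with a pseudocount of 5 or quantile normalization, 4 with only the 2 groups compared, and 0 with no filter, without small RNA genes or with length trends removed. EGC against iPGC and PGCLC gave 8 and 7 with no filter, and 2 and 3 without small RNA genes and with length trends removed. Genes shared by iPGC and PGCLC numbered 115 and 18 with pseudocounts of 0.1 and 5, 0 with no filter, 27 with quantile normalization, 32 with equal medians and 20 with library weights. Gene lists called fell to 0 with an estimated correlation in each of the 4 main comparisons. They numbered 11 and 8 with no filter for EGC and PGCLC against PGC, 3 with a pseudocount of 0.1 and 2 with a filter at 5 FPKM for PGCLC against PGC, and 2 with a pseudocount of 0.1 or only the 2 groups compared for PGCLC against iPGC.

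With the replicate number as a replicate block, genes changed were 10 for iPGC and 2 for PGCLC against PGC, 0 for PGCLC against iPGC (519 unadjusted in limma without the block), and 2 shared. Deviations of same-numbered libraries correlated at 0.0071, -0.0295 and 0.0582, so no shared deviation was seen. Whether the numbers pair samples is not stated and stays open. No paired analysis was possible for the EGC comparisons because lines 4 and 7 share no number with the other groups.

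Leaving out each library in turn, genes changed ranged from 7 to 107 for EGC, 5 to 222 for iPGC and 0 to 289 for PGCLC against PGC, 0 to 5 for PGCLC against iPGC, 5 to 17 for EGC against iPGC and 0 to 39 for EGC against PGCLC. Shared genes ranged from 0 to 167, and lists called from 5 to 6, 0 to 6, 0 to 7 and 1 to 2 in the 4 main comparisons. The lowest counts of genes came without a library of the groups derived in culture, and the list count of iPGC against PGC was 0 without PGC library 2. A group left with 1 library was assumed to vary like the others. Depth was known only approximately, and iPGC library 1, at about 2.59 M reads, was the shallowest.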

Other observations

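The tests of library scaling, of transcript length, of other-cell markers and of the chromosome 12 microRNAs were chosen after the result was seen. Sex-linked genes differed between the EGC lines. In EGC line 4, Ddx3y, Eif2s3y, Kdm5d and Uty, all on the Y chromosome, were listed at 0 and Xist was at 0.601 FPKM. In EGC line 7 they were at 2.40, 22.9, 0.0897 and 10.9 FPKM, and Xist was at 3.27 FPKM. The PGC libraries held both Xist, at 21.4 and 13.5 FPKM, and Eif2s3y, at 12.7 and 50.9 FPKM. Pmaip1, an apoptosis regulator, was at 10.4 and 6.27 FPKM in iPGCs, 5.28 and 4.52 FPKM in PGCLCs and listed at 0 in both PGC libraries, which did not pass over all genes (adjusted p = 0.0551 and 0.0756). Adjusted over the apoptosis list alone, Pmaip1 passed in both. No other member passed in iPGCs, while in PGCLCs Bax, Bbc3 and Bad were also higher and 1 member was lower. Between PGCLCs and iPGCs, 0 of 16 members passed over all genes or the list alone (camera adjusted p = 0.958). No difference between the 2 was therefore shown.

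The iPGCs and PGCLCs had 83 and 104 higher calls against PGCs, and 5 and 13 lower ones. With equal medians 34 of 46 and 36 of 54 calls were higher, but this centring removes a real shift of all genes as well as a technical one, so how much scaling contributed is unknown. The lowest bound of the exact binomial 95% intervals, 52.53%, argues only weakly against scaling as the whole source, since genes are not independent. With length trends removed the lowest bound was 83.6%. That correction leaves the shift of the all-gene median in place (0.50 in iPGCs and 0.48 in PGCLCs), and genes are not independent. The bound therefore does not decide whether transcript length contributed. In a test chosen before, genes under 1 FPKM in both PGC libraries were 3.074 times as many as independent loss would give (231 against 75.2, interval 2.756 to 3.369). Of the higher calls, 43 of 83 in iPGCs and 59 of 104 in PGCLCs were under 1 FPKM in both PGC libraries. These are fewer than the 75.2 that independent loss would give over the 5862 genes of that test. Genes truly absent from PGCs also raise the ratio. The ratio therefore does not decide whether independent loss was the source of these calls. Independent loss may still contribute to the higher calls. Loss that favours the same genes in both libraries, the number of cells per library, and the strain and origin of the cells were not tested and may contribute.

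PGC library 1 alone held 9 transcripts of the other-cell lists at 10 FPKM or more with under 1 FPKM in library 2, such as Afp (82.6), Apoa1 (53.0), Map2 (53.3), Apob (43.2) and Rbp4 (26.7), and none were found the other way. All other genes divided 251 to 184. Fisher's exact two-sided p was 0.0122, but the limits were chosen once these genes had been seen, so the test does not decide and random loss in library 2 stays open. RNA from other embryonic cells is a candidate explanation, and 13 of 15 early PGC genes were lower in library 1, against 49.9% of all tested genes. It also remains open because Ttr and Apoa2, abundant beside Afp in yolk sac, reached only 2.24% and 2.08% of Afp, Tyrobp was listed at 0, and globin genes were not analysed here. The labels describe sorted PGCs in culture without saying how these libraries were isolated, and no biological explanation was tested.

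In EGCs, microRNA genes of the imprinted region on chromosome 12 (109452823 to 109747960, GRCm38) stood out. Of 48 there, 11 were at 10 FPKM or more in an EGC library and under 1 FPKM in the 6 others, against 31 of 478 microRNA genes elsewhere. Only 3 of them, named after their values were seen, Mir379 (222 and 677), Mir758 (107 and 94.5) and Mir453 (1632 and 80.1), were seen in both EGC libraries, and 8 were listed at 0 in 1 of them. Fisher's exact two-sided p was 0.000584, but the interval was set once the cluster had been seen and ends at a counted gene, Mir3072, so the test does not decide and unreliable FPKM at short loci stays open. Mirg, a longer RNA of the region, was at 66.8 and 51.4 FPKM in EGCs and at most 2.52 FPKM elsewhere. Meg3 and Rian, maternally expressed RNAs of the same region, were at 0.00378 FPKM or less in all libraries, and Mir544, also outside the rule for named genes, was at 761 FPKM in PGC library 1. No biological explanation was tested.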
